A study of Mus musculus with 39 samples.

How the data were processed

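RNA was measured in 39 libraries of sorted mouse monocytes and macrophages, 13 groups of 3 libraries. The mice were C57BL/6 animals between 21 and 37 weeks old, per the labels. HUPO mice carried a floxed Flip gene (symbol Cflar) and a cre recombinase driven by CD11c, and control mice carried the floxed gene and were labelled CD11c+ in place of CD11ccre. Each library came from more than 400 sorted cells. Complementary DNA was made with the SMART-Seq v4 kit, libraries with the Nextera XT kit, and single 75 bp reads were sequenced on a NextSeq 500, per the labels' protocols. The same protocols name no strand-specific step, so antisense or overlapping genes are not separated here.

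The deposited values were raw counts per gene symbol, 1 table per library with 23337 symbols, per the file headers and the whole-number values. The submitters' processing notes name the mm10 build and the tools FastQC, STAR, HTSeq and Cufflinks without versions or roles. Per the series design text, the authors removed low-quality samples, the least correlated sample of some control groups and some HUPO F4/80-high samples with neutrophil transcripts, which lowers the spread seen between the libraries kept. Their FPKM values were not analysed here. Total counts ran from 3116615 to 14100712 per library, and each library had at least 1 count in 7390 to 10804 genes. A total of 3 counts over the libraries of a group corresponded to 0.105 to 0.179 CPM (counts scaled to the TMM-adjusted library total), depending on the group. Intervals and floors given for single genes cover counting error only, since reads without molecular identifiers are not independent molecules.

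Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter on the 13 groups (12450 genes), libraries were scaled by TMM (factors 0.83 to 1.16), and 1 quasi-likelihood model with a mean per group was fitted to all 39 libraries (26 residual degrees of freedom). Dispersions followed an abundance trend (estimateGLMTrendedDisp, median 2.29) and the quasi-likelihood fit was robust; the trended estimate alone was chosen for its computing time. Tests were 2-sided, and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all genes tested in the comparison. Adjusted p-values without another name come from this edgeR test, and log2 fold changes are those of the same fit at its default prior count. A prior count of 2 was used only for the log2 CPM of the list tests and of the correlations between libraries. The standard error (SE) belongs to the log2 fold change, and values per group are mean CPM ± SD with n = 3 unless stated. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so no such test was used.

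The 13 comparisons were HUPO against control in each of 6 populations, 5 comparisons between control populations, HUPO FI2 against HUPO FI1 and FI3, and the difference of the HUPO effect between FH and FI populations. A comparison over several groups took the mean of the groups' log2 values, so a gene at 0 counts in a single group can dominate it; for such genes only levels are given. When all libraries of a group had 0 counts, the fold is given as at least the ratio to 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. A fitted fold change was not used for either.

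Before the data were examined, 16 pathway lists and 12 lists of markers of other cell types were fixed, with 431 entries in all, of which 5 were matched by an older symbol and 6 were unmatched. The pathway lists were resident macrophage genes, classical monocyte genes, non-classical monocyte genes, antigen presentation by MHC class II, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, cell cycle, death receptor and apoptosis, complement, apoptotic cell uptake and scavenging, osteoclast, glycolysis and hypoxia response, oxidative phosphorylation, immediate early and heat shock, cholesterol synthesis, and interleukin-4 induced genes. The other lists were neutrophil, dendritic cell, T cell, B and plasma cell, NK cell, fibroblast, endothelial cell, erythroid, platelet, mast cell, cartilage and bone, and skeletal muscle. Several listed genes are shared by macrophages and the named type. Each list was tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 28 lists. Genes called when only the members of a list were adjusted are counted as "adjusted over the list alone".

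Genes were named by a rule fixed before the data were examined: Cflar, Itgax and Adgre1 (Emr1 in the files) in every comparison, up to 6 genes each way with the largest change among called genes with at least 32 CPM in every library of the higher side and no overlap between sides, and up to 4 members of each list with the smallest p. Lyve1, Vsig4 and, outside the comparison of ankle and blood, Spp1 were added after their values were seen. Coordinates are those of mm10 from the reference annotation, found for 223 of 227 named genes, 4 by a newer symbol. The edgeR step was tested on simulated data for the comparison of HUPO and control FH1 with 11674 genes, of which 200 were changed. The changed genes were drawn only from those with a mean of at least 32 CPM in FH1, so the rates do not cover lower genes. It recovered 0% of the genes changed 2-fold, 26% of those changed 4-fold, 26% of those changed 8-fold and 48% of those changed 16-fold, with 0 false calls among 50.

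Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a strict filter of 15 CPM in 2 libraries, a fit to only the groups compared, each library left out, the replicate number as a block, and lists with an estimated correlation. A term for sex read from Xist and Y-linked genes, limma voom without a block, and fits without libraries rich in neutrophil or fibroblast markers were added after the data were seen. The voom trend used a span of 0.1, because the default of 0.5 gave a fitted trend below 0 (lowest -0.29). The number in a sample's title was taken as the animal, so libraries with the same number were treated as from the same animal, and libraries are named by arm and number (control-1470). Deviations from the group means had a median correlation of 0.0095 in 36 pairs of libraries with the same number, from -0.014 to 0.046, and of -0.0005 in 288 pairs of different populations of an arm with different numbers. Control and HUPO libraries of a population shared no number. Some titles carry x4 or x5 after the number, whose meaning the labels do not give.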

Results

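The series measured gene expression in sorted monocytes and synovial macrophages of mice with and without arthritis. HUPO mice lack Flip (Cflar), an inhibitor of death receptor signalling, in CD11c-expressing cells, and had established arthritis, per the series design. Control mice were littermates or matched animals. Classical monocytes (CM) and non-classical monocytes (NCM) came from blood. The ankle gave populations named FH1 and FH2 (F4/80 high) and FI1, FI2 and FI3 (F4/80 intermediate), and FI2 was taken from HUPO mice only. Each of the 13 groups had 3 libraries. Control blood libraries held 4223829 to 12109347 counts and HUPO blood libraries 4957773 to 6944073. Ankle libraries held 3132775 to 14100712 counts in controls and 3116615 to 13257994 in HUPO mice.

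Cflar, the targeted gene (mm10 chromosome 1, 58711508 to 58758884), was detected in every group. In FH2 it averaged 219 ± 43.2 CPM in control and 40.7 ± 27.3 in HUPO mice (adjusted p = 0.19), and in FH1 159.7 ± 44.8 and 58.4 ± 33.3 (adjusted p = 0.692). It was not called in any HUPO comparison, and blood levels were 58.3 ± 5.05 in control CM and 52.2 ± 28.3 in HUPO CM. The counts cover the whole gene, including exons outside the deleted part, so they do not measure the deletion. Itgax, which encodes CD11c and whose promoter drives the cre (chromosome 7, 128129547 to 128150657), was highest in control FI3 (219.9 ± 65.0 CPM) and control NCM (215 ± 101). It had no counts in control FH1, HUPO CM or HUPO FI1. Emr1, now Adgre1, encodes the sort marker F4/80 and averaged 1283 ± 158 CPM in control FH1 and 1328 ± 233 in control FH2, above 356 ± 113 in control FI1 and 559 ± 252 in control FI3.

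**Figure D1:**
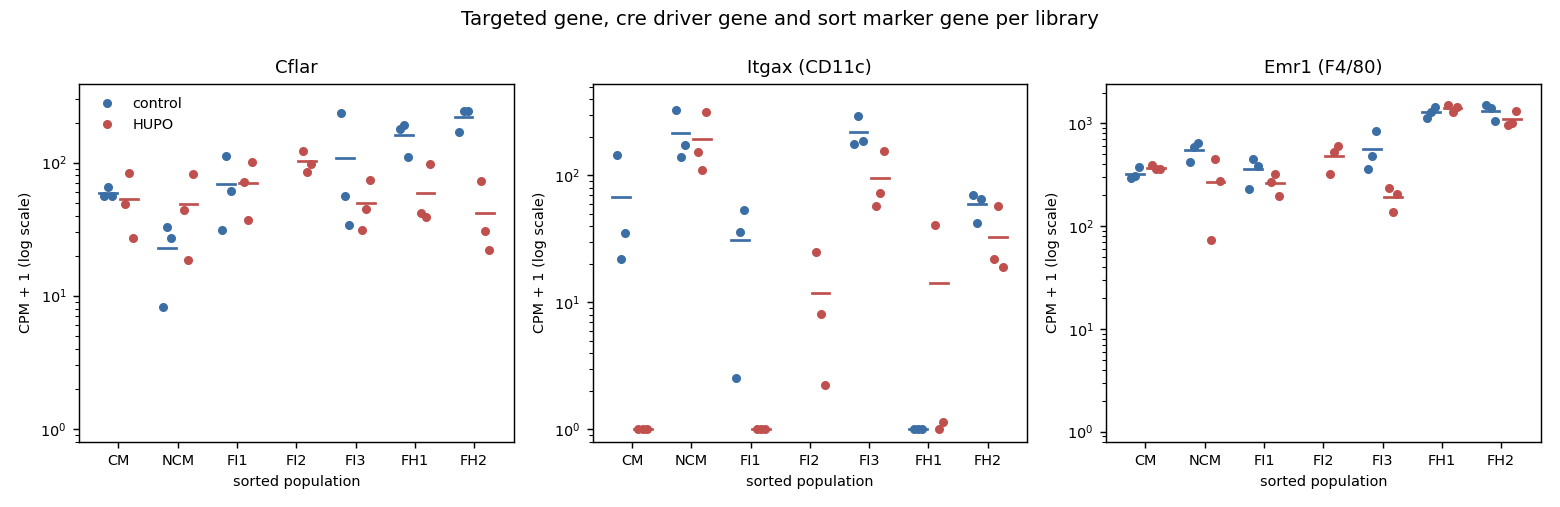
CPM + 1 on a log axis for Cflar, Itgax and Emr1 in each sorted population, with 1 point per library and a line at the mean of 3 libraries of control and HUPO mice. Emr1 averaged 1283 CPM in control FH1 and 1422 in HUPO FH1, and Itgax was at 0 in control FH1.

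Control ankle macrophages (12 libraries) were compared with control blood monocytes (6 libraries) to ask which genes differ between these sources. Any effect of cell preparation would go with the source and was not tested. Sepp1 (Selenop), a plasma selenoprotein made by resident macrophages, averaged 3504 ± 2307 CPM (SD, n = 12) in ankle and 429.7 ± 139 (SD, n = 6) in blood (log2 fold change 2.70, SE 0.26, adjusted p = 2.57e-09). The chemokine genes Ccl7 (682 ± 442 CPM) and Cxcl1 (247 ± 262 CPM) were called higher in ankle and had no counts in any of the 6 blood libraries. The complement gene C1qb averaged 3541 ± 2671 CPM against 72.4 ± 67.3. Nr4a1, a transcription factor that non-classical monocytes need, averaged 484 ± 225 CPM in ankle and 2800.2 ± 1336 in blood (log2 fold change -2.53, SE 0.20, adjusted p = 2.77e-11). Cflar was also higher in ankle (138.5 ± 82.4 against 40 ± 21.9 CPM, adjusted p = 0.00583).

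Of 28 resident macrophage genes, 23 rose and 0 fell (25 adjusted over the list alone; list adjusted p = 1.07e-27), with Folr2 at 632 ± 641 CPM in ankle and no counts in blood. Of 25 inflammatory cytokines and NF-kB targets 16 rose (18 alone; adjusted p = 4.85e-15), among them Ccl2 at 762 ± 352 against 13.5 ± 9.72 CPM. The NF-kB inhibitor gene Nfkbia was at 1980.3 ± 741 against 590.1 ± 176 CPM. Immediate early and heat shock genes rose in 12 of 20 cases and fell in 1 (16 and 1 alone; adjusted p = 2.38e-09), including Fos (log2 fold change 1.34, SE 0.19) and Jund (1.25, SE 0.15). Complement rose in 7 of 11 and fell in 1 (8 and 1 alone), apoptotic cell uptake in 8 of 17 with 1 fall (8 and 1 alone), cell cycle in 6 of 27 (10 alone) and interleukin-4 induced genes in 5 of 12 (5 alone). These lists passed at adjusted p = 2.22e-07, 0.001, 1.29e-05 and 4.47e-06. Non-classical monocyte genes fell in 11 of 15 cases (14 alone; adjusted p = 4.85e-15), and classical monocyte genes fell in 6 of 14 and rose in 2 (6 and 2 alone; adjusted p = 0.0011). Glycolysis genes rose in 6 of 17, neutrophil markers rose in 2 of 17 and fell in 2, and interferon-stimulated genes fell in 5 of 25 (adjusted p = 0.0312, 0.00907 and 0.0158, and 0.143, 0.261 and 0.241 with an estimated correlation). Of markers of other cells, platelet genes fell in 7 of 7, erythroid genes in 3 of 4, T cell genes in 3 of 9, B and plasma cell genes in 2 of 8, NK cell genes in 2 of 5 and endothelial cell genes in 2 of 5. Fibroblast genes rose in 4 of 14 (adjusted p = 0.0207, and 0.266 with an estimated correlation), and Dcn, a matrix gene, was at 187 ± 274 CPM in ankle and 0 in blood. The skeletal muscle list had 0 of 4 genes called (adjusted p = 0.537), cartilage and bone had 1 of 3 lower (0.537), mast cell had none of 5 (0.288), and death receptor and apoptosis had 3 of 25 higher and 1 lower (0.368). Spp1 (osteopontin) averaged 333 ± 450 CPM in control ankles with 0 in blood.

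In all, 1584 of 12450 genes were called, 857 higher and 727 lower in ankle, over a median shift of 0.107 of all genes. The count was 1011 without control-1194 and control-1392 of FI1, which leaves 1 control FI1 library, and 1054 with a term for sex. Whichever library was left out, 75 of 96 named calls remained called, including Sepp1, Ccl7, Cxcl1, C1qb, Nr4a1, Folr2, Ccl2, Nfkbia, Fos, Jund, Dcn, Spp1 and Cflar.

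**Figure D2:**
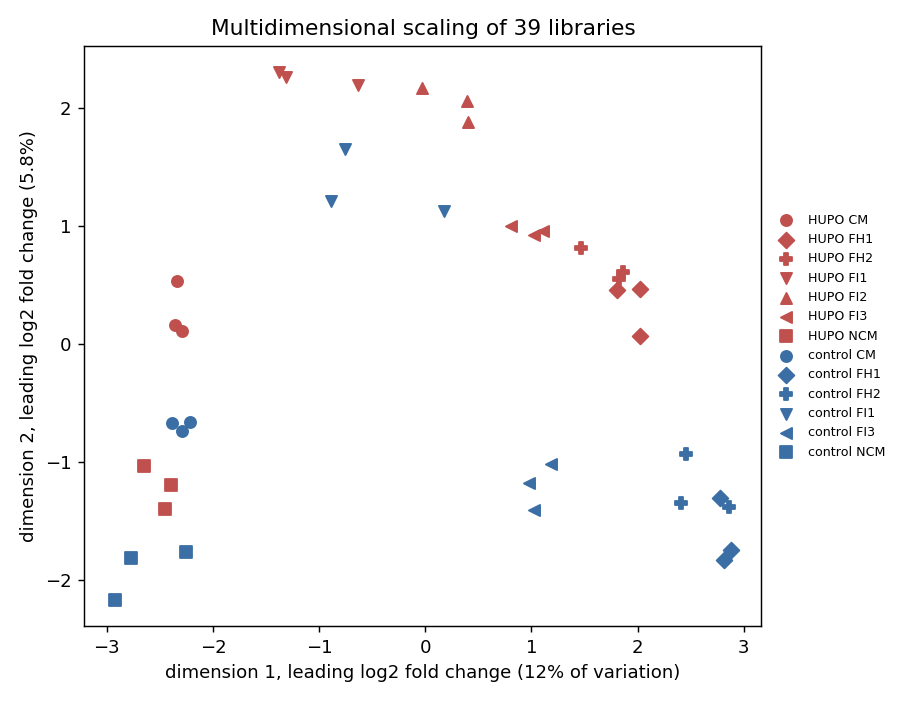
Multidimensional scaling of the 39 libraries by leading log2 fold change, with 1 point per library, marker by population and colour by arm. Dimension 1 (12% of variation) placed control FH1 libraries at 2.78 to 2.88 and control CM libraries at -2.38 to -2.21, and HUPO FH1 libraries at 1.81 to 2.02.

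NCM were compared with CM in control blood to see how the circulating subsets differ. Ly6c2, which encodes the surface marker of classical monocytes (chromosome 15, 75108158 to 75111970), was at 647 ± 218 CPM in CM and had no counts in NCM, at least 5290-fold lower (adjusted p = 3.55e-10). Vcan (versican) was at least 1270-fold lower in NCM (adjusted p = 4.96e-05) and the lipid receptor gene Trem2 at least 282-fold lower (adjusted p = 0.000105). The scavenger receptor gene Msr1 fell by 3.08 on the log2 scale (SE 0.40, adjusted p = 1.1e-05). Rgs1, a regulator of G protein signalling, rose 8.0-fold (log2 3.00, SE 0.37, adjusted p = 3.95e-06), and the tetraspanin gene Cd9 rose 7.23-fold (SE 0.37, adjusted p = 1.05e-05).

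Classical monocyte genes fell in 4 of 14 cases (11 adjusted over the list alone; adjusted p = 3.94e-22), with F13a1 (coagulation factor XIII) at 25.03 ± 21.8 against 1495 ± 386 CPM and the collagenase gene Mmp8 at least 1460-fold lower. Non-classical monocyte genes moved up together (adjusted p = 0.0045, and adjusted p = 0.0748 with an estimated correlation) with 0 of 15 called. Of 13 MHC class II genes 2 fell, H2-DMa (132 ± 35.4 against 339 ± 47.6 CPM) and H2-DMb1, and the list did not pass (adjusted p = 0.111). Cell cycle genes (0 of 27 called, 0.0328) were higher, and interferon-stimulated (0 of 25 called, 0.0441), oxidative phosphorylation (0 of 20; 0.0441), immediate early (1 of 20 fell, 0.0481) and B and plasma cell genes (0 of 8; 0.0481) gave list calls that were lost with an estimated correlation (adjusted p = 0.31, 0.333, 0.283, 0.331 and 0.248). T cell markers were lower in NCM (0 of 9 called, adjusted p = 4.96e-06) and endothelial markers higher (0 of 5 called, 0.00248). The cholesterol exporter gene Abcg1 (145 ± 33.7 against 14.8 ± 6.38 CPM) and Lta4h, of leukotriene synthesis (249 ± 37.3 against 60.8 ± 20.9), also rose. Retnla (a resistin-like protein) had a ratio of 5350 with a 95% counting interval of 960 to 212000, and its NCM level varied widely (213 ± 329 CPM). Fos fell to 566 ± 97.5 from 1518 ± 104 CPM.

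The test called 110 genes, 21 higher and 89 lower in NCM, and 73 without NCM library control-1470. Of 21 named calls, 8 remained whichever library was left out (Trem2, Ly6c2, Vcan, Msr1, Retnla, Rgs1, Cd9 and Gbp7), and the others reached an adjusted p of up to 0.26. With the animal as an additive block, edgeR called 0 genes (508 at an unadjusted p under 0.05; 2 residual degrees of freedom), where DESeq2 without the block called 1241. The block also ended 4 list calls: interferon-stimulated genes (adjusted p = 0.121), oxidative phosphorylation (0.127), B and plasma cell (0.0865), and immediate early and heat shock in control NCM vs CM (0.0814).

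FH macrophages (6 libraries) were compared with FI macrophages (6 libraries) of control ankles to describe the F4/80-high compartment. Emr1 itself averaged 1306 ± 179.7 CPM (SD, n = 6) in FH and 458 ± 207 in FI (log2 fold change 1.55, SE 0.27, adjusted p = 0.000242). The folate receptor gene Folr2 averaged 1181 ± 416 against 81.8 ± 63.2 CPM (adjusted p = 0.00468) and Sepp1 5595 ± 829 against 1414 ± 728 CPM (log2 fold change 2.05, SE 0.27, adjusted p = 3.74e-06). The integrin gene Itgb5 rose by 3.15 (SE 0.34, adjusted p = 1.15e-07) on the log2 scale. Emb (embigin) fell by 3.19 (SE 0.28, adjusted p = 1.22e-09), and Il1b (interleukin 1 beta) fell by 2.52 (SE 0.31, adjusted p = 1.08e-06).

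Resident macrophage genes rose in 7 of 28 cases (12 adjusted over the list alone; adjusted p = 1.72e-10), and apoptotic cell uptake genes in 4 of 17 (9 alone; adjusted p = 1.42e-05). Complement genes rose in 4 of 11 and fell in 1 (8 and 2 alone; adjusted p = 0.00104, and adjusted p = 0.111 with an estimated correlation), with C1qb at 5985 ± 604 against 1097 ± 999 CPM and C3 at 20.2 ± 29.0 against 287 ± 307. MHC class II genes fell in 6 of 13 and rose in 1, Ctss (adjusted p = 3.94e-05, and 0.0538 with an estimated correlation), although control FH2 held high levels. Classical monocyte genes fell in 4 of 14 and rose in 1 (6 and 2 alone; adjusted p = 2.74e-12), and neutrophil markers fell in 2 of 17 (3 alone; adjusted p = 1.48e-08). The neutrophil list summed to 20309 to 27770 CPM in control FI1 and 272 to 283 in control FI3. The control FH libraries held 5.81 to 1063 CPM, so the fall of this list rested on FI1. Ly6c2 also differed within FI, at 1788 ± 736 CPM in FI1 with no counts in FI3. Cell cycle genes (0 of 27 called, adjusted p = 0.0003), non-classical monocyte genes (3 of 15 fell, 0.0165), interferon-stimulated genes (1 up and 1 down of 25; 0.0195) and mast cell markers (0 of 5 called, 0.0145) were lower, but not with an estimated correlation (adjusted p = 0.0683, 0.111, 0.318 and 0.111). Dendritic cell markers were lower too (0 of 12 called, adjusted p = 0.0106, and 0.0691 without the 3 FI1 libraries rich in fibroblast markers). Cytip, a regulator of leukocyte adhesion, fell by 4.50 (SE 0.29, adjusted p = 2.93e-12), the protease gene Napsa by 5.22 (SE 0.57) and the leukotriene receptor gene Ltb4r1 by 5.69 (SE 0.78). Plbd1, a phospholipase-like gene, was at 0 CPM in control FH1 and 126 ± 63.3 in FH2, against 583.5 ± 85.5 in FI1 and 959 ± 226 in FI3. Olfml3 showed the opposite order, with 924 ± 143 CPM in FH1 and 388 ± 92.3 in FH2 against 12.4 ± 13.5 in FI1 and 0 in FI3.

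The test called 491 genes, 271 higher and 220 lower in FH, over a median shift of 0.167. The count was 53 with the animal as an additive block (3 residual degrees of freedom, 8 of 50 named calls remaining) and 292 without control-1194 and control-1392 of FI1, which leaves 1 control FI1 library. Leaving out 1 library at a time gave 364 to 480 calls, and 36 of 50 named calls remained in each.

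FH2 was compared with FH1 in control ankles to ask what separates the F4/80-high subsets. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), was at 33121 ± 11778 CPM in FH2 and 52.1 ± 9.10 in FH1 (log2 fold change 9.31, SE 0.55, adjusted p = 1.78e-12). H2-Aa rose by 9.83 (SE 1.03, adjusted p = 3.84e-07) and H2-Eb1 by 9.80 (SE 0.74, adjusted p = 3.64e-10). H2-DMa, which loads peptides, rose 28.1-fold (SE 0.39). In all, 8 of 13 MHC class II genes rose and 0 fell (8 adjusted over the list alone; list adjusted p = 2.25e-41).

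Classical monocyte genes rose in 3 of 14 cases (6 up and 1 down alone; adjusted p = 3.98e-05, and 0.123 in a fit to only the groups compared), with Emb at 185 ± 67.4 against 26.8 ± 16.3 CPM and Hp (haptoglobin) at 14.5 ± 10.3 against 0.400 ± 0.700. Inflammatory genes rose as a list (1 of 25 called, adjusted p = 4.23e-05), led by Il1b at 1088 ± 198 against 242 ± 169 CPM. Immediate early genes (1 of 20 called, 4 alone; adjusted p = 0.00143) and interleukin-4 induced genes (0 of 12 called, 2 alone, 0.000217) were higher too, but not with an estimated correlation (adjusted p = 0.148 and 0.0565), and the same held for cell cycle (0 of 27 called, 0.0304, then 0.248), glycolysis (0 of 17; 0.0231, then 0.172) and neutrophil genes (0 of 17; 0.0144, then 0.296). Dusp1, a phosphatase of MAP kinases, rose 2.04-fold (SE 0.20, adjusted p = 0.00432). Plbd1 was at 126 ± 63.3 CPM with no counts in FH1 (adjusted p = 7.2e-10) and Itgax at least 516-fold higher (adjusted p = 0.00942). The interferon-induced gene Ifi27l2a was the single gene called lower (log2 fold change -1.83, SE 0.37, adjusted p = 0.0107).

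The test called 49 genes, 48 higher and 1 lower in FH2, and 30 without FH1 library control-1085. Of 16 named calls 10 remained whichever library was left out, among them Cd74, H2-Aa, H2-Eb1, H2-DMa, Emb, Hp and Plbd1.

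FI3 was compared with FI1 in control ankles. Ly6c2 was at 1788 ± 736 CPM in FI1 with no counts in FI3, at least 12400-fold lower (adjusted p = 8.67e-11), and Hp was at least 7690-fold lower (adjusted p = 1.5e-10). Cd74 rose 58.8-fold to 58447 ± 5436 CPM (SE 0.47 on the log2 scale, adjusted p = 1.6e-09), and H2-Eb1 rose by 6.77 (SE 0.65, adjusted p = 5e-08). The adhesion gene Icam1 was at 1040.2 ± 597 CPM in FI3 and 43.7 ± 26.1 in FI1 (log2 fold change 4.57, SE 0.59, adjusted p = 5.62e-06).

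MHC class II genes rose in 8 of 13 cases (11 adjusted over the list alone; adjusted p = 2.39e-22), and classical monocyte genes fell in 8 of 14 (11 alone; adjusted p = 2.29e-22). Neutrophil markers fell in 8 of 17 (13 alone; adjusted p = 2.29e-22), with S100a8 at 3.03 ± 5.04 against 4498 ± 1026 CPM and the granule gene Ngp at least 30800-fold lower. The 6 FI1 libraries of both arms held 19947 to 29049 CPM of the neutrophil list in all. Resident macrophage genes were higher as a list (0 of 28 called, adjusted p = 9.68e-08), as were interleukin-4 induced genes (1 up and 1 down of 12; 8.73e-08) and dendritic cell markers (0 of 12 called, 0.00424). Inflammatory genes rose in 4 of 25 (adjusted p = 0.00187, and 0.0764 with an estimated correlation), among them Tnfaip3 and Nfkbia. Complement genes rose in 1 of 11 (0.0281), and non-classical monocyte (0 of 15 called, 0.022) and cell cycle genes (0 of 27 called, 0.0185) were lower, none with an estimated correlation (adjusted p = 0.264, 0.13 and 0.205). Immediate early genes rose in 3 of 20 (5 alone; adjusted p = 8.32e-05), with Jund up 4.05-fold (SE 0.24) and Dusp1 2.49-fold (SE 0.20). Fibroblast genes fell in 1 of 14 (adjusted p = 0.00322, and 0.189 with an estimated correlation) and cartilage and bone genes were lower (0.02), and Prg4, a joint lubricant gene, was at 5589 ± 4839 CPM in FI1 against 0.490 ± 0.50 in FI3. The receptor gene Dcstamp (osteoclast list) was at least 1260-fold higher and the chemokine gene Ccl17 at least 6430-fold higher in FI3.

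The test called 241 genes, 116 higher and 125 lower in FI3, and 111 without the 2 control FI1 libraries with the most fibroblast reads (control-1194 at 9989 CPM of the list and control-1392 at 10322) and FI1 library HUPO-1386. That fit rests on 1 control FI1 library, control-1167, which is assumed to vary like the other groups. Of 35 named calls 18 remained whichever library was left out, including Ly6c2, Hp, Cd74, H2-Eb1, Icam1, Tnfaip3, Jund, Dusp1 and S100a8.

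HUPO and control CM were compared to ask how arthritis with loss of Flip relates to circulating monocytes. Gbp2, an interferon-induced guanylate-binding protein (chromosome 3, 142620602 to 142638008), was at 1746 ± 357 CPM in HUPO and 87.0 ± 0.560 in control CM, 20.0-fold higher (SE 0.68, adjusted p = 0.000878). Gbp3 rose 8.28-fold (SE 0.64, adjusted p = 0.0149), and the interferon-induced gene Iigp1 was at least 11200-fold higher (adjusted p = 0.000575). Nr4a1 (chromosome 15, 101254269 to 101274795) fell to 424 ± 86.5 from 1884 ± 370.4 CPM (log2 fold change -2.15, SE 0.35, adjusted p = 0.00108). C5ar1, the receptor for complement C5a, fell to 11.8 ± 10.6 from 156 ± 72.8 CPM (SE 0.47, adjusted p = 7.22e-05). Il1b fell to 84.1 ± 46.2 from 295 ± 51.2 CPM (SE 0.43, adjusted p = 0.0397).

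Non-classical monocyte genes fell in 2 of 15 cases (4 adjusted over the list alone; adjusted p = 5.27e-10), Nr4a1 and the enolase gene Eno3. Interferon-stimulated genes rose in 2 of 25 (5 alone; adjusted p = 2.9e-05, and 0.0533 with an estimated correlation). MHC class II genes had 0 of 13 called (6 up alone; adjusted p = 0.0006, and 0.084 with an estimated correlation), and classical monocyte genes 0 of 14 (2 up alone; 0.00287, and 0.0533). Ly6c2 was at 2647 ± 356 against 647 ± 218 CPM but was not called (adjusted p = 0.0762). Oxidative phosphorylation genes were higher as a list (0 of 20 called, 4 alone; adjusted p = 0.00089) and cholesterol synthesis genes lower (0 of 16 called, 0.00181), and neither held with an estimated correlation (adjusted p = 0.0533 and 0.0594). T cell markers were lower in HUPO CM (0 of 9 called, adjusted p = 3.08e-09), with 8.62 to 28.2 CPM of the list in HUPO and 143 to 561 in control libraries. Platelet (0 of 7 called, 5.93e-09) and B and plasma cell markers (0 of 8; 0.00121) were lower too. Mmp14, a membrane metalloproteinase, was at least 622-fold higher (adjusted p = 0.000347) and Il18bp, an inhibitor of interleukin 18, at least 1060-fold higher (0.00843). The transcription factor gene Bhlhe40 fell 23.5-fold (SE 0.83, adjusted p = 0.00493), and Itgax was at least 461-fold lower (adjusted p = 0.0114).

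The test called 70 genes, 27 higher and 43 lower in HUPO CM. The count was 45 without control-1508, 120 without HUPO-1505, 43 without HUPO-1606, which held 4769 CPM of neutrophil markers, and 42 with a term for sex. Control CM were all male by Xist and Y-linked genes and HUPO CM were 1 male and 2 female. Gbp2, Iigp1, Nr4a1, C5ar1, Il18bp, Mmp14 and Bhlhe40 remained called whichever library was left out, and the other 8 of 15 named calls reached an adjusted p of up to 0.182.

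In NCM the same arms were compared. Gbp2 was at 1603 ± 115 CPM in HUPO and 76.3 ± 33.5 in control NCM, 21.0-fold higher (SE 0.68, adjusted p = 0.000338). H2-DMa rose 6.31-fold (SE 0.35, adjusted p = 3.1e-05), H2-DMb1 6.52-fold (SE 0.39, adjusted p = 0.000115) and Cd74 4.67-fold, to 29831 ± 1538 CPM (SE 0.40, adjusted p = 0.00254). Ly6c2 was at 49.0 ± 19.8 CPM with no counts in control NCM, at least 424-fold higher (adjusted p = 8.37e-08). Nr4a1 fell to 1214 ± 449 from 3716 ± 1346 CPM (log2 fold change -1.61, SE 0.34, adjusted p = 0.0116). Cd9 fell to 311 ± 110.4 from 1382 ± 489 CPM (SE 0.36, adjusted p = 0.000939), and Anxa1, a glucocorticoid-induced annexin, fell by 1.53 (SE 0.23, adjusted p = 0.000291).

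In HUPO NCM, MHC class II genes rose in 4 of 13 cases (8 adjusted over the list alone) and interferon-stimulated genes in 4 of 25 (9 alone), each with a list adjusted p of 7.64e-13. The interferon-induced gene Ifi47 was at 782 ± 149 against 26.3 ± 28.5 CPM. Complement genes rose in 1 of 11 (5 up and 1 down alone; adjusted p = 0.000137, and 0.0629 with an estimated correlation), the called gene being Cfb at 248 ± 118 against 8.56 ± 14.8 CPM. Classical monocyte genes were higher (1 of 14 called, adjusted p = 0.00143) and non-classical monocyte genes lower (1 of 15 called, 0.0183, and 0.11 with an estimated correlation). Dendritic cell markers were higher (0 of 12 called, 0.0183, and 0.0615 with a term for sex), and platelet (0 of 7; 0.00169) and endothelial markers (0 of 5; 0.00204) were lower. Gbp7 had a ratio of 7100 (95% counting interval 1270 to 280000; adjusted p = 1.31e-05), and Il18bp was at least 2330-fold higher (0.00291). Retnla was at 0.240 ± 0.410 against 213 ± 329 CPM and the chemokine gene Ccl2 at 0.0600 ± 0.10 against 5.88 ± 5.17.

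The test called 91 genes, 65 higher and 26 lower in HUPO NCM, with 185 without HUPO-1505 and 59 without HUPO-1739. CM and NCM shared 15 genes called higher, where independent lists of these sizes would share 0.14, and the same animals gave both populations. Ly6c2, H2-DMa, H2-DMb1, Cd74, Gbp2, Gbp7, Iigp1, Il18bp, Cd9 and Anxa1 remained called whichever library was left out. The other 14 of 24 named calls reached an adjusted p of up to 0.237.

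**Figure D3:**
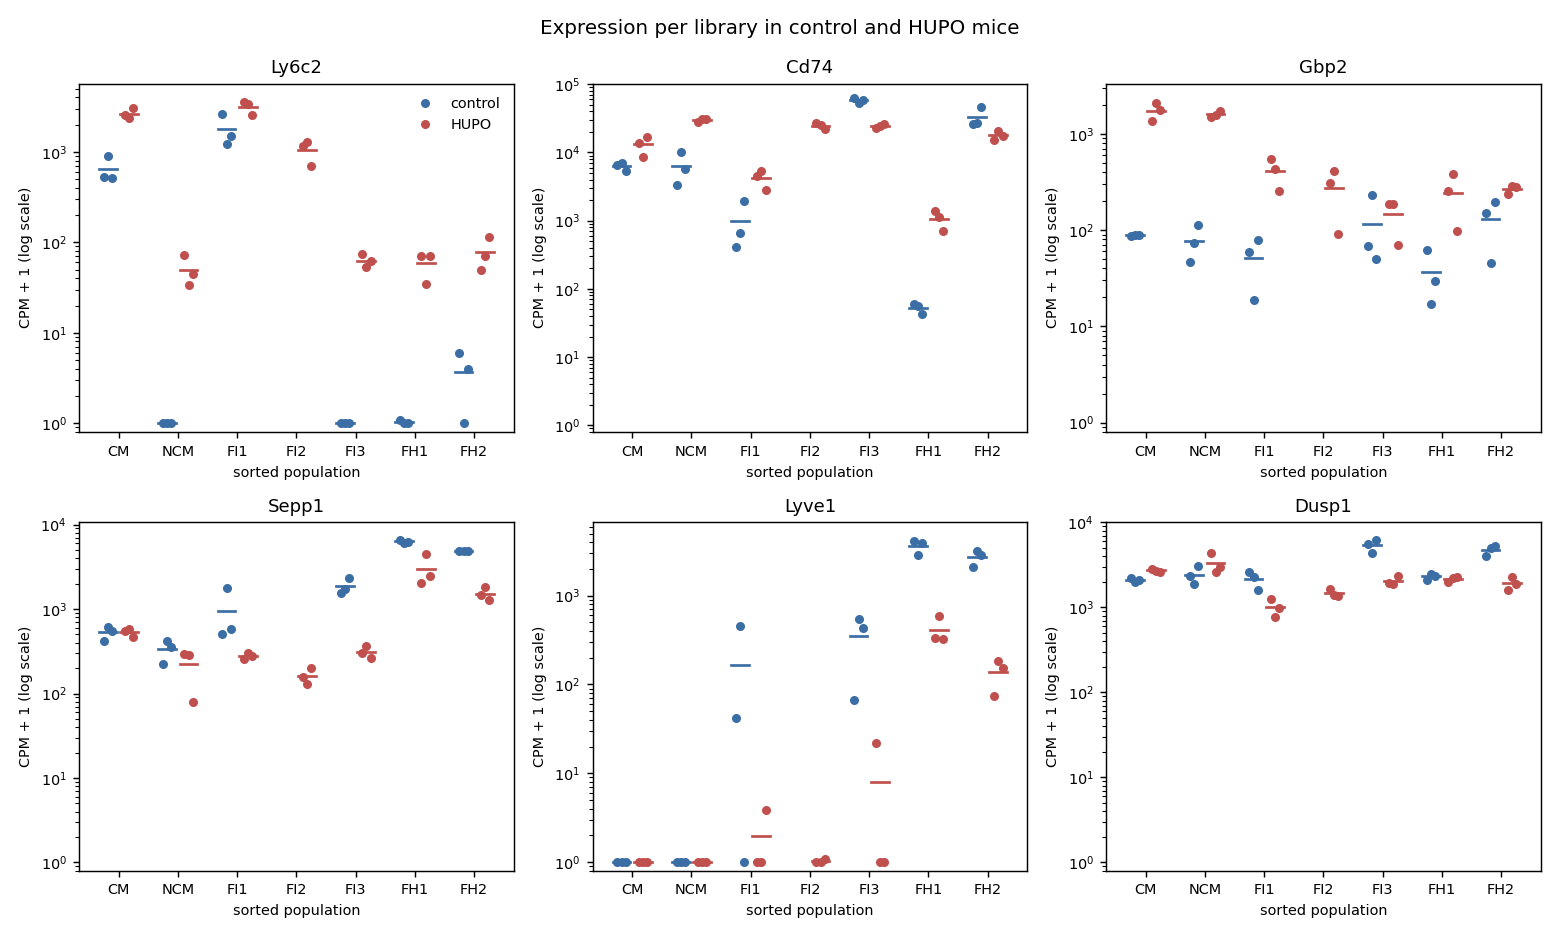
CPM + 1 on a log axis for Ly6c2, Cd74, Gbp2, Sepp1, Lyve1 and Dusp1 in each sorted population, with 1 point per library and a line at the mean of 3 libraries of control and HUPO mice. Gbp2 averaged 1746 CPM in HUPO CM against 87.0 in control CM, and Lyve1 averaged 414 CPM in HUPO FH1 against 3659 in control FH1.

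In FI1, the ankle cells with high Ly6c2 in both arms (1788 ± 736 CPM in control and 3175 ± 543 in HUPO mice), MHC class II and resident macrophage genes moved apart. Cd74 was at 4232 ± 1319 CPM in HUPO and 994 ± 810 in control FI1, 4.26-fold higher (SE 0.40, adjusted p = 0.0186), and H2-DMb1 rose 3.69-fold (SE 0.38, adjusted p = 0.0222). Sepp1 fell to 278 ± 20.9 from 949 ± 706 CPM (log2 fold change -1.77, SE 0.38, adjusted p = 0.0356). Dusp1 fell by 1.12 (SE 0.20, adjusted p = 0.0124), and Gbp2 rose 7.98-fold (SE 0.64, adjusted p = 0.0354).

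Resident macrophage genes fell in 2 of 28 cases (12 adjusted over the list alone; adjusted p = 2e-13), the other being the growth factor gene Igf1, at least 92.6-fold lower. MHC class II genes rose in 2 of 13 (9 alone; adjusted p = 2.2e-07), and non-classical monocyte genes were lower with 0 of 15 called (0.000611). Inflammatory genes (0 of 25 called, 3 down alone; adjusted p = 0.0323), uptake genes (0 of 17 called, 0.00359), immediate early genes (1 of 20 down; 0.0233) and T cell markers (0 of 9 called, 0.0103) were lower, but not with an estimated correlation (adjusted p = 0.26, 0.056, 0.26 and 0.125). Oxidative phosphorylation genes were higher (0 of 20 called, 2 alone, 0.00156, and 0.0695 with an estimated correlation). The endotoxin receptor gene Tlr4 was at 233 ± 129 against 4.73 ± 4.00 CPM, and Retnla was at least 1340-fold lower (adjusted p = 0.0124). FI1 libraries control-1194, control-1392 and HUPO-1386 held 3986 to 10322 CPM of fibroblast markers.

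The test called 28 genes, 18 higher and 10 lower, and with RLE size factors 16 higher and 15 lower. None of the 13 named calls held in every fit with a library left out (adjusted p up to 0.476): the count was 90 without control-1167, 16 without control-1194, 8 without HUPO-1170, 4 without HUPO-1231, and 11 without the libraries with fibroblast markers, which leaves 1 control library that is assumed to vary like the other groups. A fit to these 6 libraries alone with edgeR called 0 genes (519 at an unadjusted p under 0.05), where DESeq2 on all libraries called 956.

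In FI3, classical monocyte genes were higher and immediate early genes lower in HUPO than in control libraries. Whether carry-over of other cells gave the higher classical monocyte genes stayed open, as described below. Ly6c2 was at 61.9 ± 10.8 CPM with no counts in control FI3, at least 363-fold higher (adjusted p = 8.91e-08). Hp was at least 752-fold higher (adjusted p = 5.21e-08) and Vcan at least 680-fold higher (adjusted p = 0.000116). Msr1 rose 13.1-fold, to 578 ± 114 CPM (SE 0.41, adjusted p = 8.9e-07), and Ctss (cathepsin S) 2.93-fold (SE 0.18, adjusted p = 1.74e-06). Sepp1 fell to 308 ± 53.8 from 1878 ± 422 CPM (log2 fold change -2.61, SE 0.39, adjusted p = 0.000116). Dusp1 (chromosome 17, 26505590 to 26562128) fell by 1.39 (SE 0.20, adjusted p = 6.61e-05), Jund by 1.57 (SE 0.24, adjusted p = 0.000136) and Jun by 2.24 (SE 0.39, adjusted p = 0.00094). Spp1, picked out after its values were seen, was at 13811 ± 4597 against 129 ± 29.8 CPM (adjusted p = 0.0111).

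Classical monocyte genes rose in 4 of 14 cases (9 adjusted over the list alone; adjusted p = 3.4e-12), and immediate early genes fell in 7 of 20 (12 alone; adjusted p = 2.86e-11). Resident macrophage genes fell in 1 of 28 (7 alone; adjusted p = 1.86e-11). Glycolysis genes rose in 3 of 17 (4 alone; adjusted p = 1.78e-06), namely Ldha 2.51-fold (SE 0.22), Pkm2 2.54-fold (SE 0.23) and Aldoa 2.50-fold (SE 0.25). Osteoclast genes were higher (0 of 10 called, 2 alone, 0.000601) and dendritic cell markers lower (0 of 12 called, 0.00184). Neutrophil markers rose in 1 of 17 (9 alone; adjusted p = 1.24e-06, and 0.0518 with an estimated correlation), S100a9 having a ratio of 5890 (95% counting interval 1060 to 233000). Lower lists that were lost with an estimated correlation were inflammatory genes (3 of 25 fell, 0.00199, then adjusted p = 0.074), interleukin-4 induced genes (1 of 12 fell, 0.000601, then 0.0518), cholesterol synthesis (0 of 16 called, 0.00177, then 0.0523), cell cycle (0 of 27 called, 0.00927, then 0.161), mast cell (0 of 5 called, 0.0112, then 0.101) and MHC class II (1 up and 1 down of 13; 0.00347, then 0.141). Oxidative phosphorylation (0 of 20 called, 4 alone, 0.00289, then adjusted p = 0.0717) and fibroblast genes (0 of 14 called, 3 alone, 0.0222, then 0.325) were higher. Icam1 fell to 169.7 ± 58.4 from 1040.2 ± 597 CPM, and Emr1 fell to 192 ± 49.3 from 559 ± 252 (adjusted p = 0.0314). Cd300lf, an inhibitory receptor gene, was at least 765-fold higher, and Mucl1 at least 1710-fold lower.

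The test called 133 genes, 87 higher and 46 lower, and with RLE size factors 78 higher and 66 lower. The count was 80 without control-1470x4, 75 without HUPO-1170 and 76 without HUPO-1231. Ly6c2, Hp, Vcan, Msr1, Ctss, Sepp1, Dusp1, Jund, Jun, Ldha, Pkm2, Aldoa, Xaf1, Cd300lf and Serpinb1a remained called whichever library was left out, and the other 15 of 30 named calls reached an adjusted p of up to 0.306. Control FI3 were 2 males and 1 female, and HUPO FI3 were all female.

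In FH1, the control population with the least MHC class II, HUPO libraries had higher classical monocyte and MHC class II genes. Cd74 was at 1072 ± 346 CPM in HUPO and 52.1 ± 9.10 in control FH1, 20.5-fold higher (log2 fold change 4.36, SE 0.44, adjusted p = 1.76e-07). H2-Eb1 rose 22.4-fold (SE 0.59, adjusted p = 1.98e-05). Hp was at 118 ± 45.7 against 0.400 ± 0.700 CPM (log2 fold change 7.76, SE 0.78, adjusted p = 1.33e-07), and Emb rose 7.65-fold (SE 0.39, adjusted p = 1.81e-05). Csf1r, the receptor for macrophage colony-stimulating factor, fell to 1228 ± 346 from 3646 ± 446 CPM (log2 fold change -1.57, SE 0.21, adjusted p = 1.97e-05). The protease inhibitor gene Cst3 fell by 1.46 (SE 0.17, adjusted p = 9.97e-07). Spp1 was at 12614 ± 4046 against 220.1 ± 84.6 CPM (adjusted p = 0.0268).

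Classical monocyte genes rose in 6 of 14 cases (9 adjusted over the list alone; adjusted p = 1.26e-20), with Ly6c2 at a ratio of 1570 (95% counting interval 281 to 61900). MHC class II genes rose in 7 of 13 (8 up and 1 down alone; adjusted p = 6.12e-11) and glycolysis genes in 3 of 17 (3 alone; 6.37e-07), with Pkm2 up 2.45-fold (SE 0.23) and Ldha 2.29-fold (SE 0.22). Neutrophil markers rose in 1 of 17 (9 alone; adjusted p = 9.38e-20), the called gene being Il1r2 at 203 ± 118 against 7.04 ± 7.62 CPM, and FH1 library HUPO-1386 held 10544 CPM of the list. Interferon-stimulated genes rose in 3 of 25 (3 alone; adjusted p = 6.28e-05, and 0.099 with an estimated correlation), among them Gbp2. Resident macrophage genes were lower (0 of 28 called, 1 alone; 3.54e-06), as were immediate early genes (0 of 20 called, 3 alone, 0.00682), and cell cycle (0 of 27 called, 0.0284) and mast cell genes (0 of 5 called, 1 alone, 0.0339) were higher. None of these 4 lists held with an estimated correlation (adjusted p = 0.099, 0.215, 0.322 and 0.216). Saa3, an acute phase gene, was at least 1120-fold higher (adjusted p = 0.00296), and Trem1, an activating receptor gene, had a ratio of 8850 (95% counting interval 1590 to 350000). The prostaglandin-degrading enzyme gene Hpgd was at 2.80 ± 4.67 against 452 ± 83.9 CPM, and Nupr1 fell 4.35-fold (SE 0.42). Itgax was called higher (adjusted p = 0.0247) with 39.4 CPM in FH1 library HUPO-1084 and 0 and 0.140 in the other HUPO libraries, and the call ended without HUPO-1084 or any of control-1085, control-1167 and control-1194 (adjusted p up to 0.982).

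Genes often used to mark resident synovial macrophages had large differences in level that the test did not call; Lyve1 and Vsig4 were chosen after their values were seen. Lyve1 (chromosome 7, 110850607 to 110863239) was at 414 ± 148 CPM in HUPO and 3659 ± 721 in control FH1 (adjusted p = 0.692) and at 135 ± 56.5 against 2733 ± 556 in FH2 (adjusted p = 0.576). Vsig4, a complement receptor gene, was at 274 ± 213 against 5019 ± 512 CPM in FH1 (adjusted p = 0.698). Timd4, a receptor for apoptotic cells, was at 0.770 ± 1.33 against 255 ± 56.2 CPM in FH1 (adjusted p = 0.544), and Sparc was at 28.4 ± 32.8 against 3227 ± 662 (adjusted p = 0.0836). In each of these the 3 HUPO libraries lay below the 3 control libraries, and 15.6% of all genes tested in FH1 and 18.4% in FH2 had no overlap between the arms, where chance alone gives 10%, counting either order.

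The test called 105 genes in FH1, 94 higher and 11 lower, and 77 to 107 when 1 library was left out. Of 29 named calls 17 remained in each such fit, including Ly6c2, Hp, Emb, Cd74, H2-Eb1, Pkm2, Ldha, Saa3, Trem1, Nupr1, Csf1r and Cst3. DESeq2 called 449 higher and 349 lower, and a fit to the 6 libraries alone 49 higher and 49 lower, so the excess of higher calls depended on the fit.

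In FH2, Ly6c2 was at 77.7 ± 34.0 CPM in HUPO and 2.66 ± 2.51 in control mice, 27.9-fold higher (SE 0.61, adjusted p = 3.3e-05). Ctss rose 2.96-fold (SE 0.18, adjusted p = 2.29e-06) and Gngt2, a G protein subunit gene, 27.3-fold, to 181 ± 25.1 CPM (SE 0.55, adjusted p = 2.29e-06). Nr4a1 fell to 172 ± 18.1 from 757 ± 205 CPM (log2 fold change -2.13, SE 0.35, adjusted p = 0.00048), and Nupr1, a stress response gene, fell 7.36-fold (SE 0.43, adjusted p = 0.00014). Dusp1 fell by 1.31 (SE 0.20, adjusted p = 0.00015), Ier2 by 1.56 (SE 0.26, adjusted p = 0.000572) and Zfp36, which destabilises cytokine messages, by 1.53 (SE 0.27, adjusted p = 0.00125). Sepp1 fell to 1518 ± 279 from 4855 ± 26.9 CPM (SE 0.38, adjusted p = 0.0239).

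Classical monocyte genes rose in 3 of 14 cases (8 adjusted over the list alone; adjusted p = 4.08e-09) and immediate early genes fell in 4 of 20 (10 alone; adjusted p = 1.19e-08). Glycolysis genes rose in 3 of 17 (4 alone; adjusted p = 7.92e-05), with Pkm2 up 2.93-fold (SE 0.23) and Ldha 2.22-fold (SE 0.22). Interferon-stimulated genes rose in 1 of 25 (2 alone; adjusted p = 3.88e-07). Resident macrophage genes (1 of 28 fell; adjusted p = 4.9e-06) and interleukin-4 induced genes (0 of 12 called, 1 alone, 0.0292) were lower, and neutrophil (0 of 17 called, 4.93e-06) and oxidative phosphorylation genes (0 of 20 called, 0.0224) were higher, none of them with an estimated correlation (adjusted p = 0.101, 0.252, 0.101 and 0.19). FH2 library HUPO-1231 held 4507 CPM of neutrophil markers. Msr1 rose to 889.97 ± 102 from 259.7 ± 139 CPM. Apoc2, an apolipoprotein gene, was at 101 ± 5.63 against 3.15 ± 0.510 CPM, and Mef2c fell 5.48-fold (SE 0.60). Spp1 was at 19110 ± 5083 against 765 ± 844 CPM and was not called (adjusted p = 0.135).

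The test called 81 genes in FH2, 59 higher and 22 lower, over a median shift of -0.11. The count was 33 without control-1392, 45 without control-1470x4, 47 without HUPO-1170, 47 without HUPO-1231 and 45 without the HUPO libraries rich in neutrophil markers; DESeq2 called 258 higher and 518 lower. Ly6c2, Nr4a1, Ctss, Pkm2, Ldha, Dusp1, Ier2, Jund, Zfp36, Gngt2 and Nupr1 remained called whichever library was left out, and the other 15 of 26 named calls reached an adjusted p of up to 0.39.

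Calls overlapped between ankle populations. FI3 and FH2 shared 34 genes called higher (0.41 for independent lists) and 10 called lower (0.08), FI3 and FH1 shared 25 called higher (0.66), and FH1 and FH2 shared 28 (0.45). Ly6c2, Hp, Pkm2, Ldha, Aldoa, Ctss, Apoc2 and the ferritin gene Fth1 were among the genes called higher in all 3. These comparisons used different control and HUPO libraries, but some came from the same animals and all shared the estimate of spread.

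**Figure D4:**
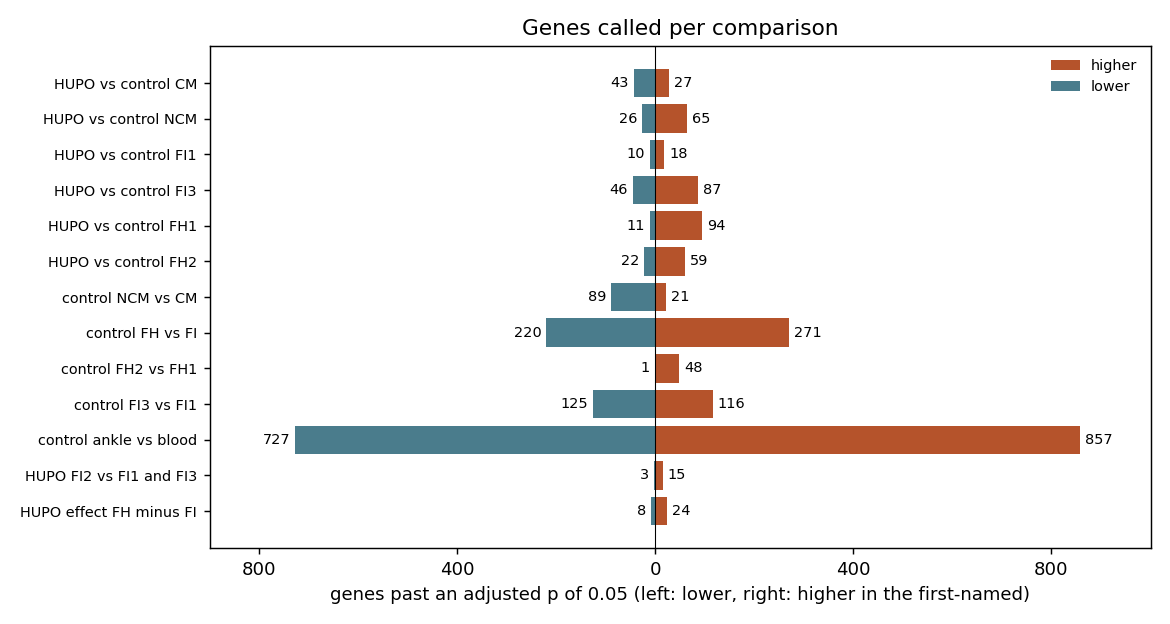
Number of genes with an adjusted p under 0.05 in each comparison, with bars to the right for genes higher and to the left for genes lower in the first-named group. HUPO against control gave between 28 (FI1) and 133 (FI3) genes per population, and control ankle against blood gave 1584.

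FI2, taken from HUPO ankles only, was compared with FI1 and FI3 of HUPO ankles. Fth1, which stores iron, was at 26828 ± 3319 CPM in FI2 against 12352 ± 4966 (SD, n = 6) in the others (log2 fold change 1.20, SE 0.16, adjusted p = 0.000265). Clec7a, the receptor for beta-glucans, rose 2.57-fold (SE 0.22, adjusted p = 0.0047) and the hyaluronan receptor gene Cd44 2.09-fold (SE 0.18, adjusted p = 0.0047). C5ar1 rose to 1313 ± 181 from 458 ± 295 CPM (SE 0.35, adjusted p = 0.0247), and Idh1 fell to 60.5 ± 18.6 from 222 ± 115 (SE 0.30, adjusted p = 0.00541). Inflammatory genes were higher (0 of 25 called, 3 adjusted over the list alone; adjusted p = 3.5e-11), as were MHC class II (0 of 13 called, 6 alone; 2.29e-07), uptake (0 of 17 called, 2 alone, 0.000376) and endothelial genes (0 of 5 called, 2 alone, 0.00773, and 0.107 with the animal as a block and 0.0819 in a fit to only the groups compared), and cell cycle genes were lower (0 of 27 called, 1.43e-11). Complement (1 of 11 rose, 4 alone, 0.00012), fibroblast (0 of 14 called, 0.000274), glycolysis (0 of 17 called, 1 alone, 0.00769), B and plasma cell (0 of 8 called, 0.00773) and interferon-stimulated genes (0 of 25 called, 0.022) were higher and oxidative phosphorylation genes (0 of 20 called, 0.0386) lower, but not with an estimated correlation (adjusted p = 0.0762, 0.102, 0.0768, 0.0762, 0.32 and 0.249). The comparison sets FI2 against the mean of FI1 and FI3, which differed: the MHC class II gene Cd74 was at 24496 ± 2262 CPM in FI2, 24334 ± 1672 in HUPO FI3 and 4232 ± 1319 in HUPO FI1.

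The FI2 comparison called 18 genes, 15 higher and 3 lower, and 6 with the animal as an additive block (4 residual degrees of freedom, 3 of 7 named calls remaining). Of the named genes only Fth1 remained called whichever library was left out; the count was 6 without FI2 library HUPO-1231, 1 without FI2 library HUPO-1386, 7 without FI1 library HUPO-1170, 4 without FI1 library HUPO-1231, 9 without FI3 library HUPO-1170, 9 without FI3 library HUPO-1231, 8 without FI3 library HUPO-1386 and 38 without the FI1 libraries rich in fibroblast markers.

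The HUPO effect was compared between FH and FI macrophages by testing the difference of the effects. It called 32 genes, 24 with a higher and 8 with a lower effect in FH, over a median shift of -0.184. Plbd1 (adjusted p = 5e-06) was at 0 in control and 30.4 ± 29.3 CPM in HUPO FH1, and at 959 ± 226 in control and 376 ± 95.4 in HUPO FI3. The count was 15 with the animal as an additive block (8 residual degrees of freedom, 3 of 12 named calls remaining), and 21 without FH1 library HUPO-1084.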

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

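The tests of neutrophil reads, of sex, and of a few genes taking most of the counts were chosen only after the results were seen, and so was the test of depth, and earlier tests of depth and of a few genes were replaced.

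What set these results apart was a difference between groups, tested directly: the HUPO effect in FH macrophages against that in FI macrophages. Of 12450 genes 32 were called. Levels are given as control and then HUPO. Vcan (adjusted p = 0.000806) was at 101 ± 68.1 and 438 ± 319 CPM in FI1, 0 and 113 ± 33.4 in FI3, 166 ± 79.7 and 78.2 ± 43.2 in FH1, and 60.3 ± 28.5 and 30.8 ± 27.6 in FH2. Traf1 (adjusted p = 0.000813) was at 94.6 ± 20.9 and 22.7 ± 10.6 CPM in FI1, 432 ± 159 and 181 ± 45.8 in FI3, 0.0800 ± 0.140 and 53.5 ± 54.0 in FH1, and 75.3 ± 43.5 and 89.6 ± 50.7 in FH2. Csf1r (adjusted p = 0.031) was at 1092 ± 254 and 665 ± 95.9 CPM in FI1, 1385 ± 201 and 1338 ± 173 in FI3, 3646 ± 446 and 1228 ± 346 in FH1, and 2564 ± 189 and 1212 ± 130.1 in FH2. Serinc3 (adjusted p = 0.031) was lower in HUPO mice in all 4, at 1856 ± 259 and 1625 ± 189.7 CPM in FI1, 2041 ± 691 and 1177 ± 120.2 in FI3, 5493 ± 750.3 and 2203 ± 147 in FH1, and 4789 ± 678 and 1584 ± 164 in FH2. Srgn (adjusted p = 0.0274) was at 1784 ± 459 and 1677 ± 566 CPM in FI1, 1483 ± 71.4 and 2528 ± 353 in FI3, 2473 ± 394 and 1822 ± 484 in FH1, and 3374 ± 827 and 1658 ± 328 in FH2. The other named genes were Plbd1 (5e-06), Atp8b4 (0.00298), Itgax (0.0049), Tbc1d8 (0.00644), Mefv (0.00644) and Xaf1 (0.0148). Of 12 named calls 8 remained whichever library was left out. Itgax ended without FH1 library HUPO-1084 (0.172), Srgn in 9 of 24 such fits (adjusted p up to 0.0753), Serinc3 in 15 (0.0776) and Csf1r in 15 (0.0906).

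As lists, the effect in FH was lower for resident macrophage genes (adjusted p = 0.00873) and higher for classical monocyte genes (0.000392), inflammatory genes (0.00412), interferon-stimulated genes (0.000284), neutrophil markers (0.00019) and mast cell markers (0.0489). None held with an estimated correlation (adjusted p = 0.509, 0.0612, 0.224, 0.224, 0.224 and 0.339). For neutrophil markers the mean difference was 0.691 and the median -0.119. Of 100 splits, 3 gave as many calls as the real one, which is 1 of them, and the highest other gave 207.

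Classical monocyte genes were higher in HUPO FI3, FH1 and FH2. Neutrophil reads in FH1 library HUPO-1386 and FH2 library HUPO-1231 were argued against as the whole cause in FH1 and FH2, since without these libraries the largest adjusted p of the list was 4.56e-08. Neutrophil reads in the other HUPO libraries cannot be told apart from other causes: in 2 of the 3 populations each HUPO library kept held more neutrophil marker reads than each control library (774 to 1917 against 272 to 283 CPM in FI3, 1880.1 and 2378 against 5.81 to 899 in FH1), and in FH2 they overlapped (309 and 1297 against 88.6 to 1063). Carry-over of blood classical monocytes into the gates stayed open, since genes high in HUPO CM had median shares at least 1.21 times those of the list. Carry-over of FI1 cells stayed open too (0.995). Monocyte-derived macrophages in arthritic ankles were not tested and also stayed open.

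Interferon-stimulated genes were higher in HUPO NCM, and in HUPO CM at the preset correlation only (adjusted p = 0.0533 with an estimated correlation, 2 of 25 called). A sex effect common to all populations was argued against for the called genes, since 6 of 6 remained called with a term for sex. That term was a single effect over all 39 libraries, so a sex effect particular to blood monocytes was not tested. Each HUPO CM library, 1 of them male, held at least 1371 CPM of Gbp2 and 591 of Gbp3. The control CM libraries, all male, held at most 87.4 and 151 CPM. A few genes taking most of the counts was argued against, since between any control and HUPO library the shares of the 10 highest genes could shift the others by a log2 of at most 0.07, against a median log2 fold change of the list of 0.85 in CM and 2.69 in NCM. These shares did differ in CM, at 9.84 to 11.3% in control and 11.4 to 12.5% in HUPO libraries, and a higher share lowers the other genes. Arthritis or loss of Flip as the cause was not tested apart and stayed open.

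Some genes had 0 reads in every library of one arm and at least 32 CPM in every library of the other, 74 in all over the 6 populations. Transcripts missed at random in single libraries were argued against as the whole cause outside FI1. In 6 of 6 populations the real split gave more such genes than each of the other 9. The real split and the highest other gave 27 and 2 genes in FI3, 10 and 2 in FH1, and 12 and 1 in FH2. The margin was smaller in blood (8 and 4 in CM, 13 and 6 in NCM). In FI1 (4 and 3) the counts were too close to decide it. Lower depth in the arm at 0 was argued against as the whole cause, since 41.9% of these genes (exact 95% interval 30.5 to 53.9) were at 0 in the arm with the higher total counts. For the others depth was not tested: the at least 578 reads that the depth of the arm at 0 would give follow from the limit of 32 CPM and the totals. The share planned as the test, 58.1% at 0 in the arm with the lower totals (46.1 to 69.5) against a limit of 60%, did not decide it. A difference in the number of transcripts captured was not tested. The arms' biology was not tested and stayed open.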

How the results depend on the processing

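No named gene that was called in the main or the alternative fit turned direction, and no list called in the main test did so. A change of sign in a gene called in neither fit was not counted. Lists were run with an estimated correlation, RLE factors, a term for sex, only the groups compared, the number as a block, and without the libraries rich in fibroblast or neutrophil markers, and not with DESeq2, voom, the other filters or single libraries left out. The FPKM alternative was not run, since the deposited values were counts. On the same libraries the number of calls depended on the model, and the effect of depth on it was not tested.

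In the order CM, NCM, FI1, FI3, FH1, FH2, NCM against CM, FH against FI, FH2 against FH1, FI3 against FI1, ankle against blood, FI2 and the difference of effects, DESeq2 called 1277, 1.1e3, 956, 1192, 798, 776, 1241, 1802, 538, 1637, 3267, 947 and 1056 genes. In the same order, limma voom with the number as a random effect called 422, 344, 168, 482, 417, 465, 667, 1771, 223, 825, 3631, 436 and 198, and without a block 423, 340, 167, 479, 414, 463, 637, 1744, 223, 815, 3677, 423 and 197. The split of higher and lower calls turned in FH2 (DESeq2 258 and 518, voom 149 and 316) and with voom in FH1 (184 and 233), where DESeq2 gave 449 higher and 349 lower, and the causes were not tested. In FH against FI voom gave 1289 and 482.

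A fit to only the groups compared called 11 in CM, 9 in NCM, 0 in FI1 (519 at an unadjusted p under 0.05), 25 in NCM against CM, 28 in FH2 against FH1, 77 in FI3 against FI1, 63 in FI2 and 52 for the difference of effects. It gave 47 higher and 64 lower in FI3, 49 and 49 in FH1, 46 and 61 in FH2, and 418 and 178 in FH against FI. The number as an additive block called 0 in NCM against CM (508 unadjusted), 53 in FH against FI, 6 in FI2 and 15 for the difference of effects. A term for sex called 42 in CM and 1054 in ankle against blood. Without the 3 HUPO libraries rich in neutrophil markers, 37 were called in CM and 45 in FH2, and without the 3 FI1 libraries rich in fibroblast markers, 11 in FI1, 292 in FH against FI, 111 in FI3 against FI1, 1011 in ankle against blood and 38 in FI2. That leaves 1 control and 2 HUPO FI1 libraries, so the spread of the lone control library is assumed to be that of the other groups, and the change in counts is not an effect of fibroblast reads alone. The causes were not tested.

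With 1 library left out at a time the counts ran from 43 to 120 in CM, 59 to 185 in NCM, 4 to 90 in FI1, 75 to 142 in FI3, 77 to 107 in FH1, 33 to 57 in FH2, 73 to 143 in NCM against CM, 364 to 480 in FH against FI, 30 to 47 in FH2 against FH1, 162 to 229 in FI3 against FI1, 1270 to 1512 in ankle against blood, 1 to 27 in FI2 and 21 to 42 for the difference of effects. Of the named results, DESeq2 left 398 of 414 on their side of the threshold, RLE 408, a term for sex 350, no filter 393, the strict filter 414 and voom 350 with or without a block. The additive block left 23 of 96, the fit to only the groups compared 278 of 406, the fit without the FI1 libraries 157 of 224 and that without the neutrophil-rich libraries 82 of 102. With single libraries left out, 3582 of 4224 cases kept their side. Of the list calls, 66 of 134 remained with an estimated correlation and 68 did not. A term for sex ended 7 of 134, RLE 4 of 134, the fit to only the groups compared 12 of 129, the block 5 of 37, the fit without the FI1 libraries 14 of 68 and that without the neutrophil-rich libraries 5 of 32.

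Other splits of the same libraries were counted. For 3 libraries against 3 they are too few for a share under 0.05: the real split and the highest other gave 70 and 8 in CM, 91 and 25 in NCM, 28 and 12 in FI1, 133 and 1 in FI3, 105 and 3 in FH1, 81 and 0 in FH2, 110 and 12 in NCM against CM, 49 and 3 in FH2 against FH1, and 241 and 13 in FI3 against FI1. In FH against FI and in ankle against blood, 1 of 100 splits, the real one, gave as many calls (491 and 1584, highest other 101 and 191). The other splits shuffled labels over all these libraries and could mix populations within a group, which the real split never does. Their share therefore does not show whether chance could give these counts. In FI2, 7 of 84 splits gave at least 18 calls. The highest, 208 and 70, set FI1 and FI3 against the rest, so the splits measured differences between populations, and their share does not show whether chance could give 18. Among splits that part as many libraries of the same animal as the real one, the highest other gave 12 in NCM against CM (4 splits), 27 in FH against FI (15), 7 in FI3 against FI1 (6), 208 in FI2 (27) and 0 for the difference of effects (4).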

Other observations

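Spp1 was chosen after its values were seen. Spp1 was at 17487 ± 6073 CPM in HUPO FI2 (n = 3), 777 ± 501 in HUPO FI1 and 219 ± 101 in control FI1. Cflar was at 101 ± 19.5 CPM in HUPO FI2, and Emr1 at 485 ± 145. Sparc was at 30.3 ± 23.0 CPM in HUPO and 1179 ± 360.4 in control FH2 (adjusted p = 0.286), and Vsig4 at 143 ± 76.8 and 1348 ± 185 (adjusted p = 0.735).

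By Xist and Y-linked genes, FI1 and FI2 libraries were all female and control blood libraries all male. FH2 library control-1085x5 carried both signals (Xist 203.6 CPM).

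The neutrophil list summed to 3333 to 6694 CPM in HUPO FI2.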
